A study of Drosophila melanogaster with 3 samples.

How the data were processed

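Chromatin immunoprecipitation with sequencing (ChIP-seq) was performed on whole *Drosophila melanogaster* embryos of mixed sex, collected 0 to 24 h after egg laying. Per the labels, the embryos came from a transgenic line that stably expresses CG12391 with a GFP tag at its C terminus, and an anti-GFP antibody was used for the immunoprecipitation. Chromatin was sonicated to fragments of 200 to 800 bp, per the labels. The 3 samples are biological replicates of this 1 group. The labels name no second genotype, stage or treatment, so no comparison between groups was made.

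Values were taken from 5 deposited peak lists on genome build dm6. There was 1 list per replicate, 1 list called on the pooled replicates, and 1 list thresholded by the irreproducible discovery rate (IDR). Such a threshold is meant to keep peaks ranked alike across replicates. Per the deposited file lists, each replicate's peaks were called on its own alignment against 1 control shared by all 3 replicates, the pooled list on all 3 alignments against that control, and the thresholded list from the other 4. The aligner, the peak caller, their versions and the IDR setting were not given in the sources used here. The deposited signal value of each peak is the authors' own measure of peak strength. It was used to rank or filter peaks within a list and to correlate replicates across shared peaks. The deposited −log10 q-value was constant in the IDR-thresholded list and reached its ceiling for 22.9% to 33.3% of the peaks in the other lists, so it was not used for ranking. Deposited summit offsets located each peak's summit.

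Each replicate list and the pooled list held exactly 30000 peaks, so their length gives no measure of depth. Read numbers were not among the values analysed here, and the depth of each library is unknown. The IDR-thresholded list held 8522 peaks with 8376 distinct intervals, since some intervals carry more than 1 summit. It was the same, peak for peak, as the 8522 pooled peaks with the highest signal, all at or above 227.2. The remaining pooled peaks that overlapped none of these, 19789 in number, are called weaker peaks. The IDR-thresholded intervals and the top peaks of the lists are not independent of the replicates, because every list was made from the same 3 alignments.

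Sequence came from the Release 6 genome assembly, whose coordinates are those of dm6, and genes from Ensembl release 115. No peak ran past the end of an arm. Summits were assigned to 1 class in the order promoter (within 500 bp of a transcription start site, TSS), 5′ UTR, coding exon, 3′ UTR, other exon, intron and intergenic. The class of other exons, which holds exons that are neither coding nor UTR, was added to the planned classes. TSSs of all genes except transposable elements and pseudogenes were used. The random expectation came from 1000 sets of positions on the same arms outside runs of N, with two-sided permutation p-values, of which the smallest possible is 0.002. For replicate overlap the test was one-sided with a smallest possible p of 0.001. Peaks were counted as shared at an overlap of at least 1 bp with the 8522 highest-signal peaks of a replicate on the chromosome arms, so that lists were compared at equal length.

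Arms were tested with exact binomial tests against their length without N. A protein-coding gene was called bound when an IDR-thresholded summit lay within 500 bp of any of its TSSs. The bound share of each of 23 gene lists was compared with all other protein-coding genes on the arms by two-sided Fisher's exact tests. For 19 consensus motifs, windows reaching 50 bp to either side of the summit were compared with a window centred 500 bp away, on a side drawn at random, by two-sided exact binomial tests of the discordant summits. The flank shares and ratios given for motifs are over the windows on both sides, so they rest on 1 more window per summit than the test. Windows of equal G+C content were drawn 500 to 3000 bp from any of the summits, 1 per summit with the same number of G and C, and compared by Fisher's exact tests. All 8-mers, both strands joined, were tested with Fisher's exact tests against both 500 bp flanks where they occurred in at least 20 windows. An 8-mer was called when it was enriched on arms 2L, 2R and X and again on the held-out arms 3L, 3R and 4. Trends with signal within the IDR-thresholded list were tested by two-sided permutation of Spearman's rho with 100000 resamples, of which the smallest possible p is 1e-05. Adjusted p-values are Benjamini-Hochberg values within each family, called at 0.05. Peaks and genes are not independent replicates, since neighbouring summits and divergent promoters share signal, so these p-values describe this peak list. Intervals are 95% exact Clopper-Pearson intervals and cover counting error only. Flanking windows were not cleared of other peaks.

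Groups, tests, gene lists, motifs, most alternatives and the rule for named genes were fixed before the data were examined. The rule names CG12391 in every list, the 20 IDR-thresholded peaks of highest signal that are overlapped by top peaks of all 3 replicates, the 5 highest such peaks over 1000 bp from any TSS, and the 3 bound members of highest signal in each gene list that passed its test. Other genes named here were chosen after their values were seen. The trends of base composition and of the TATCGATA motif with signal, and the alternatives that match G+C content or draw from the same places without matching, use weaker peaks for 8-mers, vary the class shares or require overlap in only 2 replicates, were added after seeing the data. Alternatives covered the IDR threshold, the overlap rule, the distance to a TSS, the background, the word length and each replicate left out. Leaving out a replicate kept the IDR-thresholded peaks overlapped by top peaks of the other 2, although these peaks were still called on all 3 alignments. At random positions on the real arms, no 8-mer among 31673 was called against the flanks without a planted word. A word planted in 5% of these windows ranked 1 with a recovered share of 5.06%. Random positions lack the A+T excess of the real summits, and this test used no held-out arms. The absence of calls therefore says nothing about calls driven by base composition. Gene lists were simulated with the real genes and a random bound set. Of 100 null lists of 50 genes, drawn among 13968 genes, 4 were called at an unadjusted threshold. Of 100 lists bound at 1.6 times the rate, 79 were called. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.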

Results

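The binding of CG12391-eGFP, a fly protein assayed as a transcription factor through its GFP tag, was mapped in whole embryos aged 0 to 24 h. The data consisted of 3 biological replicates of 1 group, each with its own list of peaks, a pooled list and an IDR-thresholded list of 8522 peaks. Read depth is unknown. Peak widths were nearly uniform within each replicate list, with a median of 356 bp in replicate 1, 476 bp in replicate 2 and 360 bp in replicate 3, and varied in the IDR-thresholded list, where 30.3% of peaks had the most common width of 440 bp. Signal values named with genes are the authors' values in the IDR-thresholded list on dm6.

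The first comparison asked how many IDR-thresholded peaks were among the strongest peaks of each replicate, and how alike the replicates ranked them. Ranks and top peaks of a replicate are counted on the chromosome arms, which leaves out 22 mitochondrial peaks of replicate 1, the highest with a signal above that of every peak on the arms. At the strongest site, in an intron of ush, which encodes a cofactor of GATA factors, the peak ranked 2 in replicate 1, 1 in replicate 2 and 2 in replicate 3. The next peak, in an intron of CG11050, ranked 3, 2 and 1, and a peak beside CG14100 ranked 4, 3 and 3. The peak in an intron of px, a gene of wing vein patterning, ranked 1, 4 and 4. Of the IDR-thresholded peaks, 82.1% overlapped a top peak of replicate 1, 89.4% of replicate 2 and 87.9% of replicate 3, with a mean of 86.5% ± 3.82 (SD, n = 3). Top peaks of all 3 replicates overlapped 5894 peaks, or 69.2%, against 2.36% for intervals placed at random (one-sided permutation p = 0.001, the smallest possible). An overlap above random was built into the design, since the pooled peaks were called on the same alignments. The share rose from 16.6% in the weakest quintile of IDR-thresholded peaks by signal to 99.1% in the strongest. With reciprocal overlap of at least 50% of each interval the share was 40.6%. The Spearman correlation of signal over 8263 peaks found in all lists was 0.832 between replicates 1 and 3, 0.736 between 2 and 3, and 0.644 between 1 and 2. Across peaks, which are not independent replicates, the log2 signal gave Pearson correlations of 0.868, 0.780 and 0.702 for the same pairs.

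The second comparison concerned where the protein was found relative to genes. Promoters held 4206 summits, 49.4% of the list, against 13.4% of random positions, a ratio of 3.67 (permutation p = 0.002, the smallest possible, adjusted p = 0.00233). Among the top peaks of the replicates the promoter share was 49.9% ± 2.34 (SD, n = 3). Coding exons were almost free of summits. They held 8 summits, or 0.0939%, against 13.7% of random positions. The 3′ UTRs held 0.739% against 4.44%, and the 5′ UTRs outside promoters 0.399% against 0.782%. Introns held 33.1% of summits against 39.5%, and intergenic sequence 15.4% against 27.4%. Each of these lower shares had an adjusted permutation p of 0.00233. Classes exclude each other and promoters come first, so the other shares fall as the promoter share rises. The lower shares of introns and intergenic sequence therefore do not show that they were avoided. Outside promoters, introns held a larger part of the summits than of the random positions. Of random positions matched in A+T content 3.88% lay in coding exons, 7.55% in 3′ UTRs and 0.481% in 5′ UTRs outside promoters, and against them the depletion of 5′ UTRs did not pass the test (ratio 0.829, adjusted exact p = 0.569). Other exons held 0.904% against 0.766%, which did not pass the test (adjusted permutation p = 0.182). The median distance from a summit to the nearest TSS was 533 bp, compared with 1944 bp for the weaker peaks of the pooled list. Of those weaker peaks 22.3% lay at promoters, which gave an odds ratio of 3.40 for the IDR-thresholded peaks (95% interval 3.22 to 3.59, Fisher's exact test).

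**Figure D1:**
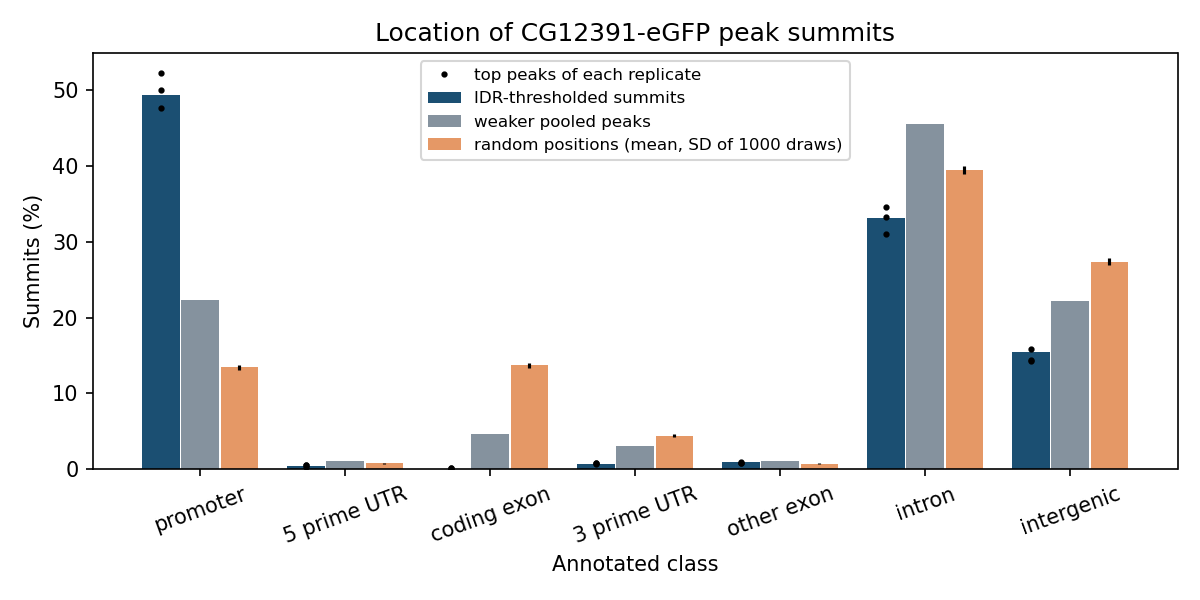
Share of peak summits (%) in each annotated class for the 8522 IDR-thresholded peaks, the 19789 weaker pooled peaks and random positions; error bars on the random bars are the SD of 1000 draws and dots are the top peaks of each of the 3 replicates. Promoters held 49.4% of IDR-thresholded summits against 13.4% of random positions, and coding exons 0.0939% against 13.7%.

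Of the 20 strongest sites 15 had their summit within 500 bp of a TSS. The summit of the top peak (2L, 480530 to 481396, signal 9277) was in an intron of ush, 1378 bp from the nearest TSS of a protein-coding gene, that of cbt, which encodes a zinc-finger transcription factor. The peak in CG11050 (2L, 6612387 to 6613002, signal 9094) was intronic and 1021 bp from a TSS. The CG14100 peak (3L, 19590390 to 19590865, signal 8433) was intergenic and 89 bp from the TSS. The px peak (2R, 22514045 to 22514545, signal 8259) was intronic, 208 bp from a TSS. Peaks close to TSSs also marked mRpL41, a subunit of the mitochondrial ribosome (signal 6804), Fkbp14, a peptidyl-prolyl isomerase (6779), Ugalt, a UDP-galactose transporter (6589), CG18549 (6314), gish, a casein kinase (6196), CG11309 (5906) and PNPase, an RNA-degrading enzyme (5779). The Lk6 peak, at a gene for a protein kinase, was intronic and 978 bp from a TSS (signal 6521). Several summits lay within 500 bp of TSSs of neighbouring genes together. These pairs were Art3 with mRpS10, Chro with Ssl1, CG9147 with Fbw5, CG5611 with Mtl, CenG1A with mRpS23, and CG11309 with CG7632. Chro encodes the chromosomal protein Chromator (3L, 22878638 to 22879159, signal 5832), and ph-p a Polycomb group protein (X, 2137108 to 2138196, signal 5744).

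The 5 strongest sites over 1000 bp from any TSS included the ush and CG11050 introns. The others were an intergenic peak 11916 bp from the TSS of CG13323 (2R, 13035076 to 13035589, signal 6077), a peak in an intron of Trl, which encodes the GAGA factor (3L, 14759243 to 14759837, signal 5966), and one in an intron of CG32772 (X, 4909981 to 4910689, signal 5299).

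The third comparison set the arms against their length. Chromosome 4, the small and largely heterochromatic arm, held 22 peaks, 0.266 times the expected number (95% interval 0.167 to 0.402, adjusted exact p = 1.15e-14, exact binomial test). Across the replicates the ratio for chromosome 4 was 0.326 ± 0.0362 (SD, n = 3). With the number of protein-coding genes as the expectation it was 0.451 (95% interval 0.283 to 0.682, adjusted exact p = 3.92e-05). Arms 2L and 3L each held 1.07 times the expected number (adjusted exact p = 0.00392 and 0.00174). The 2L excess did not pass the test when the Y was left out of the expectation (1.045, adjusted exact p = 0.0548) or when the expectation came from the number of protein-coding genes (0.967, adjusted exact p = 0.140), and the 3L excess did not pass without replicate 1 (1.05, adjusted exact p = 0.0554). With genes as the expectation the ratios of 3L and the X were 1.12 and 1.19 (adjusted exact p = 5.02e-07 and 3.41e-13). The X held 1.095 times the expected number (adjusted exact p = 0.000179) and 1.07 ± 0.0575 across replicates (SD, n = 3). The X excess no longer passed the test in the peaks shared by the other 2 replicates when replicate 2 was left out (1.05, adjusted exact p = 0.106) or replicate 3 was left out (1.05, adjusted exact p = 0.0724). It also ended in the peaks shared by all 3 replicates (1.06, adjusted exact p = 0.0682) and in the stronger 50% of peaks (1.02, adjusted exact p = 0.764). Arms 2R (0.963) and 3R (0.982) did not differ from the expectation by length. Both fell below expectation without the Y (0.939 and 0.957, adjusted exact p = 0.0123 and 0.0410) and with genes as the expectation (0.870 and 0.938, adjusted exact p = 2.02e-09 and 0.00118), and 2R also in the stronger 50% of peaks (0.924, adjusted exact p = 0.0249). No list held a peak on the Y, and whether peaks were searched for there is not given in the sources used here.

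The fourth comparison asked which groups of genes had a summit at a TSS. Of 13968 protein-coding genes 4801 were bound, or 34.4%, and the replicates gave 4805 ± 200.4 bound genes (SD, n = 3). Of the 23 gene lists 9 were bound more often than the other genes and 6 less often. Among genes of the cytoplasmic ribosome 77 of 93 were bound, or 82.8% (95% interval 73.6 to 89.8, adjusted exact p = 8.16e-21, Fisher's exact test), with RpL7 (signal 2325), RpS27 (2325) and RpL34b (2296) the strongest. The share in the replicates was 83.5% ± 0.621 (SD, n = 3). Mitochondrial ribosomal protein genes were bound in 48 of 73 cases, or 65.8% (adjusted exact p = 3.26e-07), led by mRpL41, mRpS10 and mRpS23. When each summit was given to the gene of its single nearest TSS, 30.1% of these genes were bound and the list did not pass (adjusted exact p = 0.420). The mRpS10 and mRpS23 peaks lay nearer to the TSSs of Art3 and CenG1A.

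Genes of the cell cycle and DNA replication were bound in 28 of 37 cases (75.7%, adjusted exact p = 1.45e-06), with PolD2, a DNA polymerase subunit (signal 3020), Cdk1 (1265) and aurA, a mitotic kinase (1104), the strongest. Of the proteasome genes 25 of 32 were bound (78.1%, adjusted exact p = 1.45e-06), led by Rpn3, Rpn11 and Rpn5 of the regulatory particle. General transcription genes were bound in 36 of 63 cases (57.1%, adjusted exact p = 0.000598), among them the RNA polymerase II subunits Polr2B and Polr2J and the Mediator subunit MED27. This call ended under the single nearest TSS (34.9%, adjusted exact p = 0.193) and within 100 bp of a TSS (19.0%, adjusted exact p = 0.257). Translation factors were bound in 28 of 52 cases (53.8%, adjusted exact p = 0.00806), with eIF4EHP, a repressor of cap-dependent translation (signal 5258), eIF6 (3142) and eEF1gamma (1824) the strongest.

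Oxidative phosphorylation genes were bound in 47 of 84 cases (56.0%, adjusted exact p = 0.000174), with the complex I subunits ND-MWFE, ND-ASHI and ND-24 the strongest. This call ended among peaks shared by the other 2 replicates without replicate 1 (38.1%, adjusted exact p = 0.0982) or without replicate 3 (36.9%, adjusted exact p = 0.0926), and among peaks shared by all 3 replicates (34.5%, adjusted exact p = 0.150).

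Among Polycomb and trithorax group genes 16 of 22 were bound (72.7%, adjusted exact p = 0.000765), led by ph-p (signal 5744), the chromatin remodeller gene brm (3625) and the histone methyltransferase gene E(z) (2539). Genes of insulator and architectural proteins were bound in 13 of 18 cases (72.2%, adjusted exact p = 0.00298), with Chro (5832), Cp190 (3819) and M1BP (1940) the strongest. In the stronger 50% of peaks the calls for Polycomb and trithorax genes, cell cycle genes, translation factors and oxidative phosphorylation ended, with adjusted exact p of 0.0685, 0.0520, 0.106 and 0.347. Within 100 bp of a TSS the Polycomb and trithorax call also ended (27.3%, adjusted exact p = 0.112).

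None of 179 chemosensory receptor genes was bound, with an upper 95% bound of 2.04% (adjusted exact p = 2.78e-32). Cuticle protein genes were bound in 2 of 120 cases (Cpr67Fa1 and Cpr72Eb, signals 239 and 230.2), and odorant-binding protein genes in 2 of 51 (Obp83g and Obp99b, 341 and 324). Adjusted p-values were 2.00e-18 and 1.18e-06. Male germline genes were bound in 3 of 35 cases (Mst85C, twe and bol, adjusted exact p = 0.00113). Of 115 histone genes 4 were bound (adjusted exact p = 3.09e-15), namely His2Av, His3.3B, His3.3A and His4r, the last chosen after its value was seen. These lie outside the tandem histone repeats, in which near-identical copies share reads and peaks are uncertain. Neural genes were bound in 2 of 21 cases, elav (signal 3593) and pros (263), with an adjusted exact p of 0.0292. The neural call ended without replicate 2 (9.52%, adjusted exact p = 0.0831), in the stronger 50% of peaks (0.106), under the single nearest TSS (0.214) and within 100 bp of a TSS (0.618), where the male germline call ended too (0.139).

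The remaining 8 lists did not pass. Vacuolar ATPase genes were bound in 17 of 33 cases (adjusted exact p = 0.0630), segmentation genes in 3 of 19 (bcd, cad and wg, adjusted exact p = 0.130) and Hox genes in 1 of 8 (Antp, adjusted exact p = 0.355). Muscle genes were bound in 5 of 21 cases, ecdysone response genes in 5 of 11, ovarian germline and piRNA genes in 5 of 18, Notch pathway genes in 7 of 19 and heat shock genes in 9 of 25. Adjusted p-values of these 5 lists lay between 0.442 and 0.836. With only genes that had any pooled peak within 500 bp as the background, 7 lists passed in place of 15. These were the genes of both ribosomes and of oxidative phosphorylation, bound more often, and the chemosensory, cuticle, neural and muscle genes, bound less often. Muscle genes passed in this setting (33.3%, adjusted exact p = 0.0409) and not in the main one. Segmentation genes passed only without replicate 1, bound less often (5.26%, adjusted exact p = 0.0351).

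**Figure D2:**
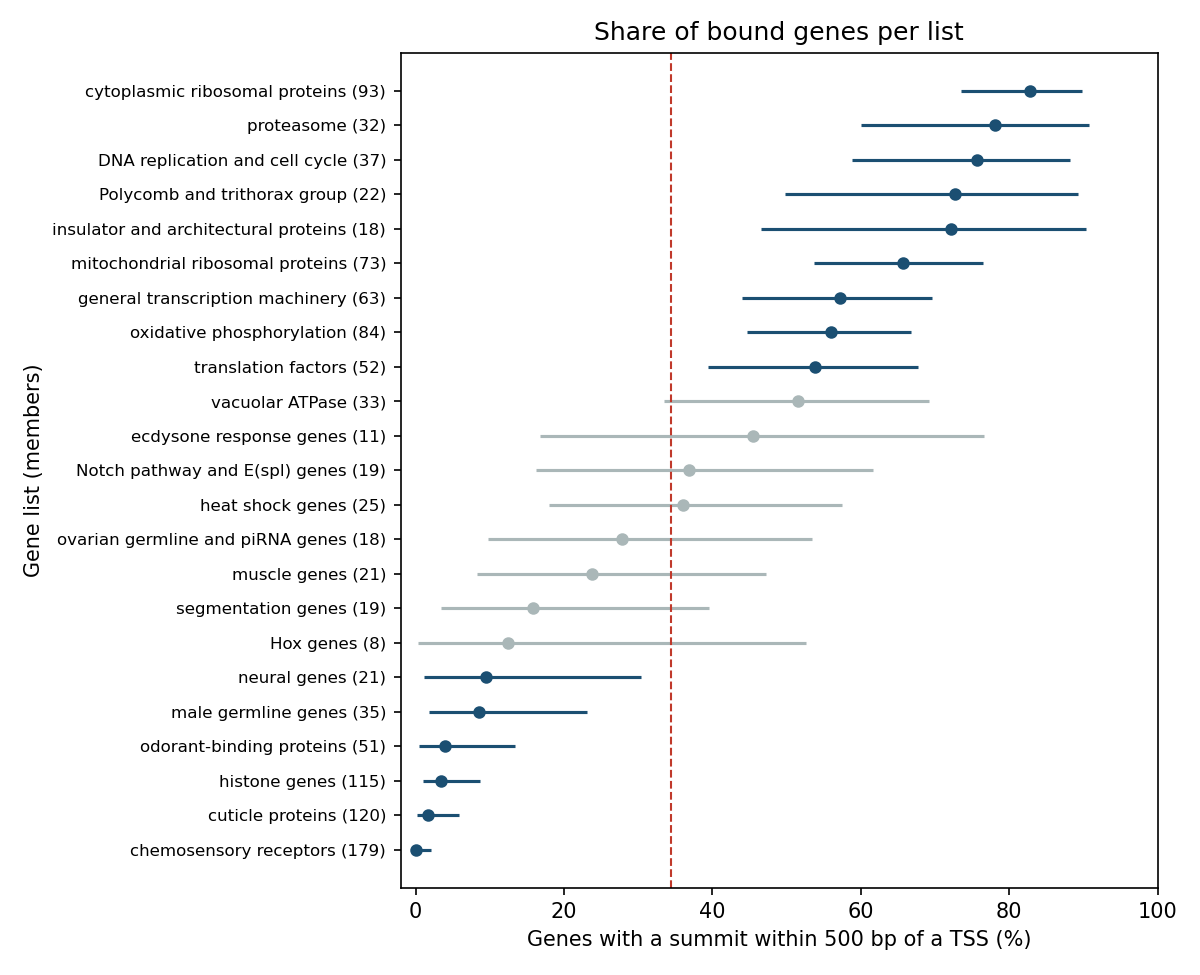
Share of genes (%) with an IDR-thresholded summit within 500 bp of a TSS, per gene list with its number of members; points are shares, bars 95% exact binomial intervals, dark points lists with an adjusted p below 0.05, and the dashed line the 34.4% over all protein-coding genes. Cytoplasmic ribosomal protein genes had 82.8% bound and chemosensory receptor genes 0.

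The fifth comparison concerned the sequence under the summits. Summit windows were 68.4% A+T against 55.7% in their flanks, an excess of 12.7 percentage points. The excess was 9.30 in replicate 1, 13.5 in replicate 2 and 10.4 in replicate 3, a mean of 11.1 ± 2.20 (SD, n = 3), and 4.01 at weaker peaks. Summits near TSSs and summits farther away had excesses of 13.01 and 12.42. Of 19311 8-mers tested on both sets of arms 1652 were called, including all 136 that consist of A and T only. The leading word, AAAATATT, occurred at 7.94% of held-out summits against 2.03% of flanks (ratio 3.90, adjusted exact p = 3.03e-45). TTTAAAAA had a ratio of 4.72 (adjusted exact p = 3.28e-53). Against windows of equal G+C content, 20 8-mers were called. AAAATATT then had a ratio of 1.30 (adjusted exact p = 0.184), and the leading words were ATCGATAG (ratio 6.48, adjusted exact p = 4.36e-11), TATCGATA (7, adjusted exact p = 2.21e-11) and GGTCACAC (8.23, adjusted exact p = 4.81e-07).

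**Figure D3:**
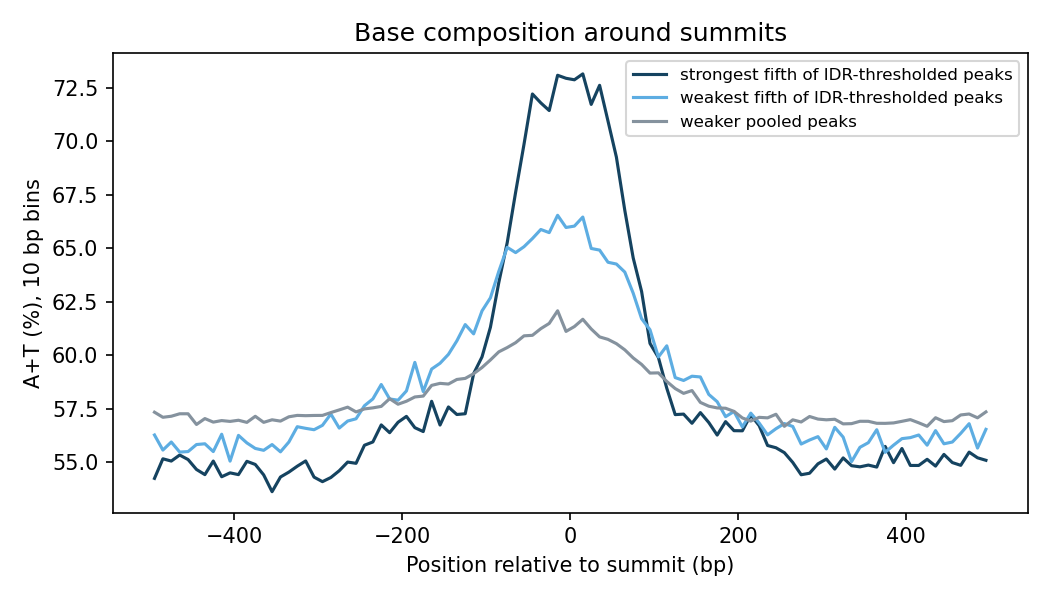
A+T content (%) in 10 bp bins against position relative to the summit (bp) for the strongest and weakest quintile of the IDR-thresholded peaks by signal and for weaker pooled peaks; the vertical axis does not start at 0. A+T content reached 73.1% at the summits of the strongest quintile, 66.5% in the weakest quintile and 62.1% at weaker peaks.

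Of the 19 fixed motifs 18 differed between summits and flanks. TATCGATA, bound by DREF and BEAF-32, which act at promoters and domain borders, occurred at 2.41% of summits against 0.217% of flanks (ratio 11.1, adjusted exact p = 6.07e-41). Among the replicates its share was 2.57% ± 0.394 (SD, n = 3). By position relative to the summit, TATCGATA was found at 40 summits in the bin starting at 0 bp. Bins starting at −80, −40, 80 and 100 bp held 57, 64, 53 and 47 summits with the word, and those at −60 and −20 bp 36 and 40. The bins starting at −500 and 480 bp held 3 and 4. TATCGATA was thus spread broadly over both sides of the summit, without a sharp maximum at it. GGTCACACT, the core promoter element bound by M1BP, was found at 1.17% against 0.106% (ratio 11.1, adjusted exact p = 7.28e-22). CATCNCTA, or Motif 7, had a ratio of 2.96 (adjusted exact p = 3.31e-09), and CGATA, the short BEAF-32 site, of 1.46 (adjusted exact p = 4.70e-22). Against windows of equal G+C content 7 motifs passed. These included TATCGATA (ratio 7.07, adjusted exact p = 6.03e-33), GGTCACACT (16.7, adjusted exact p = 3.28e-22), Motif 7 (2.22, adjusted exact p = 4.25e-07) and the short BEAF-32 site (1.45, adjusted exact p = 3.22e-21). The other 3 were the CTCF core (1.77, against 0.705 with flanks), CACACACA repeats (0.563) and A tracts (0.749, against 1.39 with flanks). At summits over 500 bp from a TSS, TATCGATA occurred at 0.301% against 0.209% (adjusted exact p = 0.383) and GGTCACACT at 0.185% against 0.0579% (adjusted exact p = 0.253). Motif 7 (ratio 1.12, adjusted exact p = 0.270) and the short BEAF-32 site (0.923, adjusted exact p = 0.165) did not pass there either.

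TATAAA (ratio 2.70), TAATTA (2.15), GTATTTT (2.23), TTTATG (1.44) and TGCATACTT, the Su(Hw) core (2.17), were also more frequent at summits than in flanks. GAGAGAG (0.329), GCCATN, the Pho site (0.631), CANNTG (0.775), CACGTG (0.463), CAGGTAG, the Zelda site (0.504), and RGWYV (0.972) were less frequent. None of these 11 passed against windows of equal G+C content. The initiator TCAGTY did not pass the test against flanks (ratio 0.929, adjusted exact p = 0.0611), and was less frequent at summits without replicate 3 (0.881, adjusted exact p = 0.00835), in windows reaching 100 bp (0.932, adjusted exact p = 0.0281) and against weaker peaks (0.862, adjusted exact p = 0.000487). The Su(Hw) call rested on 26 summits and ended without replicate 1 (2.59, adjusted exact p = 0.0846) and without replicate 3 (2.11, adjusted exact p = 0.150). The Zelda call ended at summits over 500 bp from a TSS (0.621, adjusted exact p = 0.218) and against weaker peaks (0.978, adjusted exact p = 1), the call of A tracts against weaker peaks (1.06, adjusted exact p = 0.208), and that of RGWYV in windows reaching 100 bp (0.998, adjusted exact p = 0.0758).

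The sixth comparison asked whether strong and weak sites within the IDR-thresholded list differed. From the weakest to the strongest quintile by signal the promoter share rose from 40.7% (95% interval 38.3 to 43.0) to 61.6% (59.2 to 63.9), with a Spearman's rho of 0.135 over peaks (permutation adjusted p = 1.33e-05). The share with AAAATATT rose from 6.04% to 9.74% (rho 0.0548, adjusted p = 1.33e-05), and the A+T excess from 9.51 to 17.1 percentage points (rho 0.214, adjusted p = 1.33e-05). For these 3 trends the unadjusted p was 1e-05, the smallest possible. TATCGATA went the other way, from 2.70% in the weakest quintile and 3.28% in the middle one to 1.06% in the strongest (rho −0.0418, adjusted p = 0.00014). The share of peaks overlapped by top peaks of all 3 replicates also rose, from 16.6% in the weakest quintile to 99.1% in the strongest. The trends with signal thus ran alongside replicate overlap and were not separated from it. The q-value could not be used as another ranking because it was constant in this list.

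**Figure D4:**
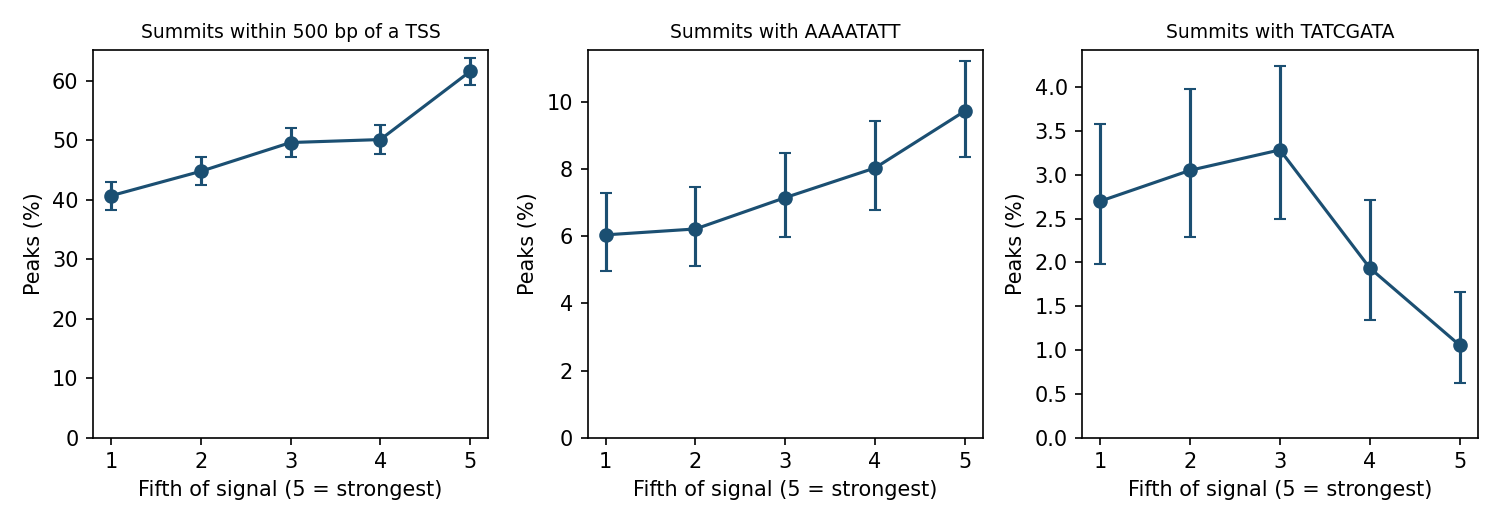
Share of peaks (%) with a summit within 500 bp of a TSS, with AAAATATT and with TATCGATA, by quintile of signal in the IDR-thresholded list (5 is the strongest); points are shares and bars 95% exact binomial intervals. The promoter share rose from 40.7% to 61.6%, while TATCGATA was at 1.06% in the strongest quintile.

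Last, the tagged gene itself was examined. CG12391 lies on the minus strand of 2R at 11147602 to 11150068. No IDR-thresholded peak lay in the gene or within 2000 bp of it. In replicate 1, 7 peaks lay there, the strongest with its summit 2 bp from the TSS (11149888 to 11150243, signal 144 in that list, rank 2100). Replicate 2 had 1 peak there (rank 14601) and replicate 3 also 1 (rank 22989). The pooled list held 3, the highest at rank 21533.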

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

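The tests on the tagged gene were chosen after its peaks were seen. The mitochondrial genome, which no comparison above used, held 22 peaks in replicate 1 and 0 in replicates 2 and 3. It was picked out because a signal appeared in data outside the main measurement, above the 3 counts that a count of 0 allows if counts are independent. Summits on the same molecule in lists of fixed length are not independent, so this bound served for selection only and is no test. The 22 summits lay in 15 intervals covering 8695 bp, ranked no lower than 4308 in the full list of replicate 1, and reached a signal of 4444, compared with 1859 for the highest peak on the chromosome arms. With a single control for all replicates and no read counts, the origin of these peaks was not tested.

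Replicate 1 also listed 7 summits in CG12391 or within 2 kb of it, against 1 in replicate 2 and 1 in replicate 3. Of 2117 other protein-coding genes within 20% of its length, 0 had an excess of 6 or more summits over both other replicates. Whether replicate 1 would list more peaks everywhere without a limit could not be tested, because each replicate list stops at 30000 peaks. Its list held 29978 peaks on the arms against 30000 in each other replicate. This near equality follows from the limit and decides nothing about the 7 summits. Across the arms, 1 of 21273 windows of 6467 bp had such an excess. These windows were tiled from the start of each arm, so a cluster that crosses an edge is split. The summits at CG12391 are themselves split this way, so this count does not measure how rare such an excess is. Extra DNA copies of the tagged gene in the transgenic line may still contribute and cannot be told apart from the other candidates here, because such copies would give several summits in every replicate, while replicates 2 and 3 together held 2, and libraries of unknown depth can differ in how many they list. Binding of the protein at its own promoter in 1 replicate was not tested, since the design gives no group that separates it.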

How the results depend on the processing

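The alternatives with G+C-matched windows and with unmatched windows of the same places, for the class shares, with weaker peaks as the background for 8-mers, without arm Y, for the signal trends, and those requiring overlap in only 2 replicates were chosen after seeing the data. No paired analysis was possible because there was only 1 group. Taking the top of the pooled list in place of the IDR-thresholded list changes nothing by construction, since they hold the same peaks, and ranking by q-value could not be run. Of the 70 alternative values of the main results, 62 kept their direction and their side of the threshold or stayed within the replicate spread, 6 of them by this construction. Leaving out each replicate gave a promoter share of 50.2% to 52.8%, an overlap of 73.5% to 78.8%, a rank correlation of 0.644 to 0.832 (highest without replicate 2), 6 called classes, 14 to 15 called lists, 17 to 18 called motifs and 1240 to 1434 called 8-mers. The left-out replicate still contributed to every interval and signal. Apart from overlap and rank correlation, these values rest on 6261 to 6717 peaks in place of 8522. A call lost there may reflect the shorter list and not that replicate. With 100 bp or 1000 bp around a TSS the promoter share was 20.01% or 58.5%, against random shares of 3.25% and 23.4%. The overlap of all 3 replicates with summits within 100 bp was 60.8%, from 100 draws with a smallest possible p of 0.01.

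With only genes that have any pooled peak as background, 7 gene lists were called instead of 15; histone genes (100%, adjusted exact p = 0.392) and male germline genes (75%, adjusted exact p = 1) reversed, on few genes each, as did Notch pathway (46.7%) and ecdysone response genes (62.5%), uncalled throughout. De novo 8-mers fell from 1652 to 884 at summits over 500 bp from a TSS, 375 against weaker peaks, 918 against unmatched windows 500 to 3000 bp away and 20 against G+C-matched windows of the same places; 456 6-mers were called. Against G+C-matched windows 7 fixed motifs passed instead of 18, and the ratios of GAGA factor (1.03), Zelda (1.19), CTCF core (1.77), initiator (1.02), DPE (1.00), Caudal (0.926), homeodomain core (0.939) and poly A tract (0.749) reversed. Without the matching, the same places and test gave 18 motifs and no reversal, so the matching accounts for these reversals. The Su(Hw) core reversed against weaker peaks (0.694) and the short BEAF-32 site at summits over 500 bp from a TSS (0.923), as did arm 2L with genes as the expectation (0.967) and other exons against weaker peaks (0.847). Uncalled lists also changed direction: ovarian germline genes in the stronger 50% of peaks, with overlap in all 3 replicates and without replicate 3 (27.8% each) and within 1000 bp of a TSS (44.4%), ecdysone response genes in the stronger 50% (18.2%), and Notch pathway (0) and heat shock genes (8%) within 100 bp. The cause was not tested. Among the other values, mostly for single classes, lists, motifs and arms, 498 alternatives agreed, 57 of them by the same construction, 46 lost their call, 10 gained one and 23 reversed. Unknown depth limits what the absence of a peak shows: a gene without a summit may have a site below the threshold, as the 34.4% of bound genes holds for this threshold only, and in the stronger 50% of peaks 10 lists were called.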

Other observations

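The tests on base composition and on TATCGATA and GGTCACACT were chosen after related values were seen; those on positions of equal A+T content and on divergent promoters were fixed before their results. Genes outside the protein-coding set had lower bound shares than the 34.4% of protein-coding genes, with intervals that excluded this value except for snRNA genes. Of 290 tRNA genes 58 had an IDR-thresholded summit within 500 bp of their TSS (20%, 95% interval 15.6 to 25.1). Of 32 snRNA genes 7 were bound (21.9%, 9.28 to 39.97), of 269 snoRNA genes 20 (7.43%, 4.60 to 11.2) and of 3289 other ncRNA genes 343 (10.4%, 9.40 to 11.5). Genes of one class often lie side by side and can share a summit. The bound genes among the insulator and architectural list, named after their values were seen, included those for DREF (Dref), BEAF-32, M1BP, CTCF, Su(Hw) and GAGA factor (Trl).

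Of the 20 strongest sites 6 lay within 500 bp of TSSs of more than 1 gene, such as Art3 with mRpS10 and CG5611 with Mtl. The hypothesis that promoter summits favour divergently transcribed pairs, whose TSSs lie within 1000 bp, was tested against the weaker promoter peaks. Of 4206 IDR-thresholded promoter summits 41.4% lay at such pairs, against 14.96% of 4406 weaker promoter summits, a ratio of 2.77 (Fisher's exact p = 3.37e-169). Random promoter positions gave 19.8%, a share above that of the weaker summits, and no test was made against them. Weaker peaks leave out any that overlap an IDR-thresholded peak, so the ratio of 2.77 depends on this comparison set. Within 100 bp of a TSS the shares were 49.7% and 22.6%, and from 100 to 500 bp 35.9% and 9.99%. The protein may thus be found more often at divergent promoters than at other promoters, although neither promoter activity nor open chromatin was measured and both remain open.

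The A+T-rich summits were weighed next. Promoter location is argued against, since summits over 500 bp from a TSS kept an A+T excess of 12.4 percentage points. A preference of the assay for A+T-rich DNA wherever it lies would give promoters no more summits than A+T-matched random positions, 13.7% of which lay at promoters, against the observed 49.4%. For the A+T excess itself this stays open, and it cannot be told apart from sequence preference, because 3.58% of such positions lay in IDR-thresholded peaks and the peaks are too few to hold more than 14.5% of equally A+T-rich bases. Of the 8-mers made of A and T only, 0 were called as enriched against windows of equal G+C, but 135 against windows of the same places without the matching. This fits with base composition as a candidate source of their enrichment. A tracts were less frequent at summits than in windows of equal G+C (ratio 0.749, adjusted exact p = 4.42e-09). Words of A and T were therefore not all alike at equal composition.

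The core promoter words were weighed as well. TATCGATA was 1.72 times as frequent at IDR-thresholded promoter summits as at weaker ones (4.56% against 2.66%, Fisher's exact p = 1.83e-06). For this word, that argues against location within 500 bp of a TSS alone. GGTCACACT, at 2.19% against 1.75% (Fisher's exact p = 0.162), did not pass this test. The kind of promoter was not held fixed, since 41.4% of the IDR-thresholded and 14.96% of the weaker promoter summits lay at divergent pairs. A difference in kind of promoter therefore remains open. Base composition alone is argued against by the TATCGATA ratio of 7.07 with windows of equal G+C. Whether the protein meets these words through their own factors, such as DREF or BEAF-32, or through open promoters remains untested. TATCGATA declined to 1.06% in the strongest peaks. That another feature sets the strongest sites apart is a hypothesis and was not tested.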
